A study of Drosophila melanogaster with 12 samples.

How the data were processed

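Small RNAs were sequenced from dissected ovaries and testes of *Drosophila melanogaster* of control flies (X^X females and X^Y males in the labels) and of flies with an added Y chromosome. There were 6 groups of 2 biological replicates: X^X, X^X/Yohio and X^X/Ycongo ovaries, and X^Y, X^Y/Yohio and X^Y/Ycongo testes, written XX, XXYohio, XXYcongo, XY, XYYohio and XYYcongo below. Per the labels' protocols, flies were reared on molasses medium at 23 °C with 14 hours of light and were 2 days old. RNA was extracted with Trizol and checked on a gel, and libraries were made with PrepX reagents on an Apollo 324 robot with 15 PCR cycles. The 12 libraries were pooled and read as single ends over 50 cycles.

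Per the submitters' processing notes, Trim Galore and Bowtie 1.1.1 were used. The genome build, the annotation, the treatment of reads that map to several places and the source of the scale factors are not given in the sources used here, so no coordinates are printed. The authors deposited 1 table per tissue, and tests were run only within a table because the tables were normalized separately. The columns headed Cs were assigned to the Yohio groups, because each table held the 3 genotypes of its tissue and the Congo and control columns were named outright; the labels do not spell out Cs, so every Yohio value rests on this reading. All 12 sample columns were used.

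The deposited values of replicate 1 of XX and of XY were whole read counts. For the other 10 libraries the authors deposited a normalized signal, which was whole read numbers multiplied by 1 factor per library: 100% of these values came out whole within 0.01 of a read. The value of 1 read in the ovary table was 1 and 0.699 in XX replicates 1 and 2, 0.574 and 0.734 in XXYohio, and 0.387 and 0.441 in XXYcongo. In the testis table it was 1 and 0.403 in XY, 0.822 and 0.533 in XYYohio, and 0.817 and 0.851 in XYYcongo. Each deposited table also holds a p-value per feature, and 100% of these matched a one-way analysis of variance of the 3 genotypes on the deposited values within 1%. In the authors' deposited table for ovary 355 of 968 features had such a p-value under 0.05, and in the authors' deposited table for testis 23 of 845.

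The ovary table lists 384 transposon and repeat entries (TE), 308 tRNA (tDNA), 234 snoRNA, 15 mitochondrial and 9 mitochondrial tRNA entries. It also lists 6 telomeric, 6 spike-in, 2 rDNA, 2 satellite and 2 Suste entries. The testis table lists 298 TE, 310 tRNA, 186 snoRNA, 16 mitochondrial, 12 mitochondrial tRNA, 7 satellite, 6 telomeric, 6 spike-in, 2 rDNA and 2 Suste entries. The TE class also holds repeats that are not transposons, such as RSP and NTS_DM. Plus and Minus give the strand of the listed entry. Gene symbols for all 566 ovary and all 524 testis entries with FlyBase identifiers came from the BDGP6.54 annotation, used for names only. Identical tRNA gene copies share their reads: 259 tRNA entries in ovary and 264 in testis had all 6 values in common with another entry. For the deposited values, counts of tRNA entries called are therefore given beside counts of distinct value profiles where the 2 differ. Read totals, class shares and ratios between classes sum all entries, so values in common enter once per entry. The 1 telomeric entry that has all its values in common with TART_B1 is not counted separately from it in the text on named elements.

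Genotypes were compared with limma 3.58.1 in R 4.3.3, using eBayes with a trend on log2(value + 1). The tests, the feature lists, the rule for named features and a first set of alternatives were fixed before the data were examined. All 3 genotypes of a tissue entered 1 model, which left 3 residual degrees of freedom. Features with a mean of at least 5 over the 6 libraries were tested and spike-ins were left out, which gave 791 features (631 profiles) in ovary and 618 (446 profiles) in testis. Tests were two-sided, adjusted by Benjamini-Hochberg within each contrast and called at an adjusted p under 0.05. Every adjusted p of a feature is from limma unless another tool is named. Fold changes are on the log2(value + 1) scale, which understates the changes of low features, and ± after a fold change is its standard error. The prior degrees of freedom were 9.59 in ovary. They were infinite in testis, where the error of each feature was taken from the trend alone. A two-sided exact test of 2 against 2 libraries cannot go below p = 0.333, so class shares have no p-value.

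There were 28 feature lists. For 18 of them no feature was tested, because the tables used here list no miRNA, hairpin siRNA or piRNA cluster entries; these 18 include every list of cell type markers. The 8 lists with at least 3 tested features were LTR retrotransposons of the gypsy, mdg1 and mdg3, copia and BEL/Pao groups, LINE elements, DNA transposons with terminal inverted repeats (TIR), telomere retrotransposons and rDNA retrotransposons. They were tested with camera, preset correlation 0.01, over 6 contrasts (48 tests adjusted together) and again with an estimated correlation. Helitrons (DNAREP1_DM) and the Y-linked repeat Suste have 2 features each and are described by member. The rule for named features took, for each contrast with a control, the 8 largest called rises and the 8 largest called falls whose libraries did not overlap, plus the 6 smallest p of each direction where fewer than 6 were called. It added up to 8 features shared by both Y chromosomes or by both tissues, the measured telomere and rDNA retrotransposons and Y repeats, and up to 4 of each list that passed. Features outside the rule are named as chosen after their values were seen.

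Total reads in the tables, spike-ins included, were 1191919 and 1557968 in XX, 1642017 and 1331653 in XXYohio, and 3113215 and 2628848 in XXYcongo ovary. They were 1221060 and 2052470 in XY, 2659310 and 1412669 in XYYohio, and 3014632 and 888745 in XYYcongo testis. Replicates correlated across features (log2 values) at r = 0.974, 0.981 and 0.975 in XX, XXYohio and XXYcongo and at 0.947, 0.931 and 0.951 in XY, XYYohio and XYYcongo. Their read numbers differed by more than sampling noise (chi-square per degree of freedom 16.1 to 229), which does not show whether they came from separate RNA.

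Replicate numbers are given by the labels. Deviations from the group mean correlated between same-numbered libraries at r = 0.41, 0.35 and 0.40 in testis, above 0.1 in each of the 3 pairs of groups, so the numbers were read as pairing testis libraries. In testis 16 features were called between the replicate numbers. A block for the replicate number leaves the testis counts at 4, 10 and 0, and its value is printed where it changes a call.

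The alternatives fixed with the tests were pseudocounts of 0.5 and 5, no filter, a mean of at least 20, TMM and median-of-ratios scaling, limma without the trend, only the 2 genotypes compared, an adjusted p under 0.1, a replicate block, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads with the deposited factors. Alternatives chosen after seeing the data were scaling to the snoRNA total, to the non-spike total and to the spike-ins with a replicate block, merging identical entries, and leaving out testis libraries with a replicate block. The tests were tried on simulated data drawn from the real means. In the simulated XXYcongo against XX ovary comparison (791 features) limma called 50% of 100 features changed 2-fold and 95% of 100 changed 4-fold, and 1.18% of the unchanged ones. In the simulated XYYcongo against XY testis comparison (618 features) it called 10% and 49%, and 1.44% of the unchanged ones. It called 0 features in simulated XXYohio and XYYohio comparisons in which none was changed, and edgeR also called 0. The simulated noise was independent between features, rises and falls were balanced, and the scale factors were exact. These rates therefore cannot expose a wrong factor, a shift of most features in 1 direction or a deviating library.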

Results

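Small RNAs of ovaries and testes were profiled in *D. melanogaster* controls, labelled X^X (females) and X^Y (males), and in flies with an added Y chromosome of 1 of 2 origins, labelled X^X/Yohio, X^X/Ycongo, X^Y/Yohio and X^Y/Ycongo. In fly notation a caret can mark attached chromosomes, which the labels do not spell out. The groups are written XX, XXYohio, XXYcongo, XY, XYYohio and XYYcongo below, as the deposited tables leave the caret out. Each of the 6 groups had 2 libraries. The contrasts set by the series design ask how each added Y chromosome changes the small RNAs of each sex relative to its control. The tables list transposons and other repeats, tRNA, snoRNA, rRNA, mitochondrial and satellite entries by strand. Non-spike reads were 897596 and 1285309 in XX, 1537728 and 1114251 in XXYohio, and 2663239 and 2427476 in XXYcongo ovary. In testis they were 589490 and 1310076 in XY, 686497 and 1164314 in XYYohio, and 714771 and 672218 in XYYcongo. The Yohio groups are those headed Cs in the deposited tables.

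TE small RNAs made up 43.8% ± 2.32 of non-spike values in XXYcongo ovary (SD, n = 2), against 24.1% ± 2.38 in XX and 26.1% ± 4.45 in XXYohio. The tRNA share was 10.7% ± 2.97, 6.81% ± 0.793 and 7.32% ± 1.94 in the same order. Identical tRNA entries were each counted, which raises this share and the read totals and lowers the shares of the other classes. snoRNA made up 6.60% ± 1.12 in XXYcongo, 9.41% ± 0.702 in XX and 9.05% ± 0.00702 in XXYohio. Fragments of the 45S rDNA unit took 56.0% and 61.5% of values in XX, 60.8% and 51.4% in XXYohio, and 36.5% and 37.1% in XXYcongo. In testis the TE share was 18.6% ± 8.32 in XY, 16.0% ± 6.13 in XYYohio and 20.01% ± 5.02 in XYYcongo. The tRNA share there was 14.7% ± 5.77, 15.1% ± 2.80 and 17.1% ± 6.11, and the snoRNA share 1.93% ± 0.114, 1.85% ± 1.09 and 2.04% ± 0.490. The 45S rDNA share varied within each testis genotype, at 66.6% and 38.7% in XY, 49.2% and 66.1% in XYYohio, and 59.1% and 36.5% in XYYcongo. The testis shares of TE, tRNA, snoRNA and 45S rDNA overlapped between genotypes. Between same-numbered libraries, the tRNA share was higher in XYYcongo than in XY (10.6% to 12.8%, and 18.8% to 21.4%) and the 45S rDNA share lower. The other differences of these classes from XY changed sign between the numbers. Satellite shares did not overlap between XY (0.185% and 0.273%) and XYYcongo (0.311% and 0.756%). Mitochondrial shares did not between XY (0.126% and 0.152%) and XYYohio (0.114% and 0.0713%).

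**Figure D1:**
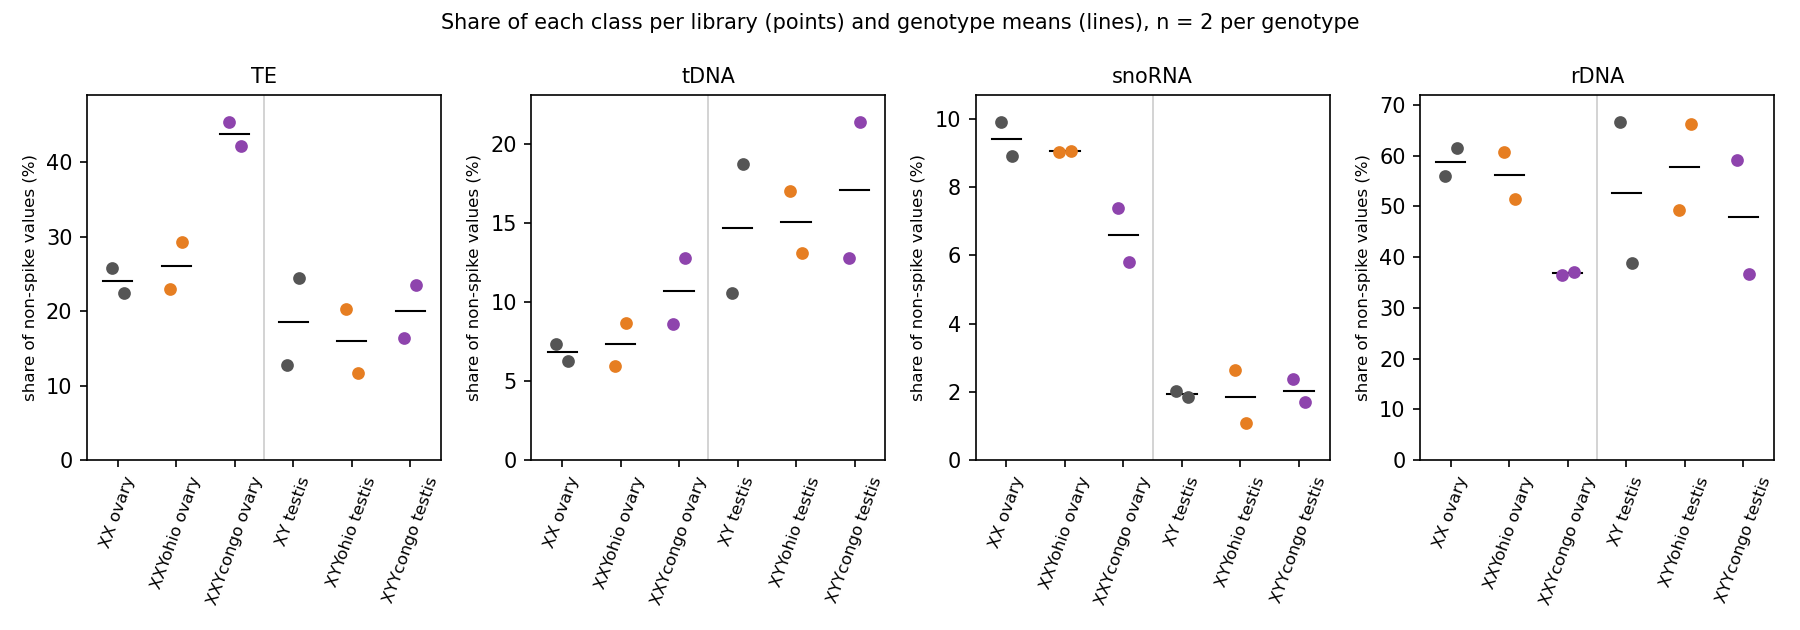
Share of non-spike values (percent) held by TE, tRNA, snoRNA and rDNA entries in each library, with points for libraries and lines for the mean of 2. TE shares were highest in the 2 XXYcongo ovary libraries, with a mean of 43.8% against 24.1% in XX.

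The XXYohio ovary was compared with the XX ovary. Small RNAs from Suste, a Y-linked repeat, rose on both strands: the Minus strand read 440 and 381 in XX and 4291 and 5726 in XXYohio (log2 fold change 3.59 ± 0.25, n = 2 per group, adjusted p = 1.75e-06), which is 12.1-fold. The Plus strand rose by 1.46 ± 0.27 (adjusted p = 0.00831). DMHMR1 Plus rose from 78 and 48.9 to 1586 and 1765 (4.74 ± 0.28, adjusted p = 3.37e-07), and DMHMR1 Minus by 3.11 ± 0.34 (adjusted p = 0.000148). PROTOP_B Plus, of the hoppel family of DNA transposons, rose from 432 and 347 to 1626 and 1757 (2.12 ± 0.23, adjusted p = 0.000136), and PROTOP Plus by 1.85 ± 0.24 (adjusted p = 0.000485). Among LTR retrotransposons, Chimpo_LTR Minus rose by 2.54 ± 0.35 (adjusted p = 0.000587), Chimpo_I Minus by 1.83 ± 0.21 (adjusted p = 0.000209) and QUASIMODO_LTR Plus by 1.89 ± 0.37 (adjusted p = 0.0115). Limma called 20 features up and 6 down of 791, and 109 had an unadjusted p under 0.05. The median over all features was 0.096 as deposited, 0.03 with TMM and 1.33 with spike-in scaling. TMM scaling gave 16 up and 7 down, and a replicate block 29 and 13. With spike-in scaling and a replicate block 2 were called, DMHMR1 Plus and Suste Minus. Leaving out XXYohio replicate 2 gave 12 up and 24 down, leaving out XXYcongo replicate 2 gave 27 and 13, leaving out XX replicate 1 gave 14 and 1, and leaving out XX replicate 2 gave 12 and 4. Suste Plus lost its call without XX replicate 2 (1.15, adjusted p = 0.1002), and QUASIMODO_LTR Plus without XX replicate 1 (1.44, adjusted p = 0.124) or XXYohio replicate 2 (1.59, adjusted p = 0.0853), and with TMM or median-of-ratios scaling.

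Of the 6 falls in XXYohio ovary, those of smallest p were on both strands of TART, a telomere retrotransposon that maintains chromosome ends in flies. TART Minus fell from 4174 and 4474 to 1100 and 1430 (−1.78 ± 0.22, adjusted p = 0.000367) and TART Plus from 2447 and 2256 to 706 and 911 (−1.55 ± 0.26, adjusted p = 0.00352). The AAGAG satellite Minus strand read 45 and 32.9 in XX and was at 0 in both XXYohio libraries (−5.30, adjusted p = 0.00971), the largest fall. Against a floor of 3 reads per library it was at least 19.8-fold lower. DM412B_LTR Plus (−2.09 ± 0.47, adjusted p = 0.0251), QUASIMODO2-LTR_DM Minus (−1.36 ± 0.29, adjusted p = 0.0182) and DMRT1C Minus (−1.26 ± 0.28, adjusted p = 0.0251) also fell. These last 4 calls each need particular libraries. The AAGAG and QUASIMODO2-LTR_DM calls ended without XX replicate 1 (adjusted p = 0.113 for both) or XX replicate 2 (0.0720 and 0.1002), and that of QUASIMODO2-LTR_DM also without XXYohio replicate 2 (0.124). The DMRT1C call ended without XX replicate 1, XX replicate 2 or XXYohio replicate 1 (adjusted p = 0.124, 0.126 and 0.282), and the DM412B_LTR call without XX replicate 1 or XXYohio replicate 1 (0.309 and 0.237). TART Plus had an adjusted p of 0.0588 without XX replicate 1. With limma without the trend 13 rises and 1 fall, TART Minus, were called. Scaling to the snoRNA total ended the DMRT1C, QUASIMODO2-LTR_DM and DM412B_LTR calls, and spike-in scaling ended every fall.

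Of the 8 telomere retrotransposon features, 2 fell (TART on both strands) and 6 did not pass in XXYohio ovary; adjusted over the list alone 3 fell. HETA Plus differed by −0.66 (adjusted p = 0.208), HETA Minus by −0.46 (adjusted p = 0.368), TAHRE Minus by −0.36, TAHRE Plus by 0.11, TART_B1 Plus by 0.59 (adjusted p = 0.373) and TART_B1 Minus by −0.14. The list had a median of −0.41 and passed camera's test downwards (adjusted p = 0.00323; adjusted p = 0.998 with an estimated correlation). The median was −0.48 with TMM scaling and turned to 0.87 with spike-in scaling, under which no telomere member was called. None of the 4 rDNA retrotransposon features passed, with R1_DM Plus at −0.59 (adjusted p = 0.251), R1_DM Minus at −0.26, R2_DM Minus at 0.12 and R2_DM Plus at −0.05 (list adjusted p = 0.408). The other lists did not pass: 4 of 26 DNA transposon features rose (adjusted p = 0.477, with a median of −0.04 against a mean of 0.21 and a test upwards), and 5 of 113 gypsy features (adjusted p = 0.864). In the LINE list 3 rose and 1 fell of 60 (adjusted p = 0.994; adjusted over the list alone 5 and 2), in BEL/Pao 1 of 27 rose (adjusted p = 0.0893; with TMM it passed downwards at 0.0383, and at 0.983 with an estimated correlation it did not; adjusted over the list alone 1 rose and 1 fell) and in mdg1 and mdg3 1 of 32 fell (adjusted p = 0.435). No copia feature of 12 passed (adjusted p = 0.864). For DNA transposon, gypsy, copia and mdg1 and mdg3 features the counts adjusted over the list alone equalled those over all features. The Helitron entry DNAREP1_DM, INE-1, read 119 and 95.1 on the Minus strand in XX and 45.9 and 49.9 in XXYohio (−1.14 ± 0.29, adjusted p = 0.0543), and its Plus strand differed by −0.43.

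No tRNA or snoRNA feature was called by limma in XXYohio ovary (30 of 229 tRNA and 11 of 194 snoRNA features at an unadjusted p under 0.05). Among tRNA features edgeR and DESeq2 also called 0, with 30 each at an unadjusted p under 0.05. Among snoRNA features edgeR called 0 with 8 at that level, and DESeq2 called U31:54Ed, named after its values were seen, with 8.

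The XXYcongo ovary differed from the XX ovary in many more features: 360 were called up and 34 down of 791 (283 and 33 of 631 profiles). Of 339 TE features 242 rose and 4 fell, with a median log2 fold change of 1.13. Suste Minus read 6842 and 10817 in XXYcongo (4.39 ± 0.25, n = 2 per group, adjusted p = 1.59e-07) and DMHMR1 Plus 2533 and 3566 (5.58 ± 0.28, adjusted p = 4.57e-08). Of 229 tRNA features 108 rose (31 of 73 profiles), and of 194 snoRNA features 25 fell and 1 rose. The scaling moves this balance. The median over all features was 0.74 in the deposited values, −0.0007 with TMM, 0.0098 with median-of-ratios, 0.52 with non-spike total, 1.03 with snoRNA total and 1.60 with spike-in scaling. The count was 179 up and 149 down with TMM, 181 and 150 with median-of-ratios, and 396 and 13 with snoRNA total scaling. With spike-in scaling and a replicate block it was 95 up and 0 down, with 246 at an unadjusted p under 0.05. Leaving out 1 library at a time gave 286 to 387 calls.

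With TMM, 90 TE features rose and 10 fell, 87 tRNA features rose and 25 fell, and 100 snoRNA features fell. TE medians were 0.37 with TMM and 2.03 with spike-in scaling, tRNA medians 0.20 and 1.76, and both stayed positive under all 6 scalings. These tRNA counts and medians take each identical entry separately. As deposited the tRNA median was 0.91 over entries and 0.80 over distinct profiles. Profile values with the other scalings are not given here. The snoRNA median was −0.29 as deposited, −1.02 with TMM and −0.003 with snoRNA total scaling, and turned to 0.62 with spike-in scaling. Each of the TE, tRNA and snoRNA changes came with the lower 45S rDNA share of the XXYcongo libraries given above, and 45S_rDNA Plus itself fell from 502704 and 552431 to 375811 and 397678 (−0.45 ± 0.17, adjusted p = 0.0445). That call ended without any 1 of XX replicate 1, XX replicate 2, XXYcongo replicate 1 or XXYcongo replicate 2 (adjusted p = 0.153, 0.284, 0.172 and 0.0799) and with snoRNA total scaling (adjusted p = 0.592). With TMM, median-of-ratios and non-spike total scaling the fall of 45S_rDNA Plus was larger and called (−1.22, −1.21 and −0.67, adjusted p = 0.0047, 0.00427 and 0.00341). With spike-in scaling its change turned to 0.48 and was not called. The other strand went the other way: 45S_rDNA Minus, named with Plus after the values were seen, rose from 68 and 69.2 to 244 and 95.8 (1.15 ± 0.38, adjusted p = 0.0246). That call ended without XX replicate 1 (adjusted p = 0.0850), XX replicate 2 (0.0873) or XXYcongo replicate 1 (0.312), and with TMM (0.530), non-spike total (0.0634) or spike-in scaling.

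**Figure D2:**
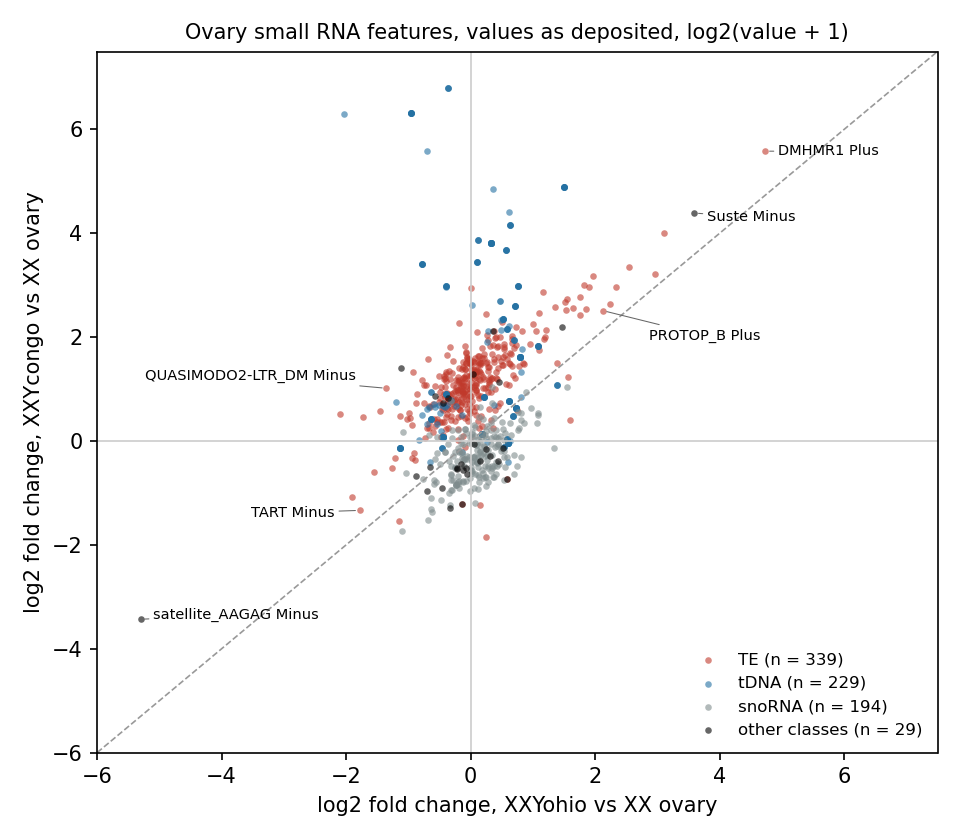
Log2 fold change against XX ovary in XXYohio (x axis) and XXYcongo (y axis) for 791 features, coloured by class (339 TE, 229 tRNA, 194 snoRNA and 29 others), with a dashed line of equality and limma values as deposited. TE features lie mostly above the line, with a median of 1.13 in XXYcongo, which TMM scaling lowers to 0.37; the snoRNA median of −0.29 turns to 0.62 with spike-in scaling.

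Among gypsy-group LTR retrotransposons 87 of 113 features rose, 2 fell and 24 did not pass in XXYcongo against XX ovary (adjusted over the list alone 90 and 2). The list had a median of 1.21 and camera's adjusted p was 1.87e-05 (adjusted p = 0.998 with an estimated correlation, as for each list that passed). Chimpo_LTR Minus rose by 3.35 (adjusted p = 7.99e-06) and Chimpo_I Minus from 545 and 491 to 4033 and 4318 (3.01, adjusted p = 5.83e-07). GYPSY2_LTR Minus rose from 26 and 25.9 to 242 and 175 (2.94 ± 0.32, adjusted p = 1.43e-05) and GTWIN_I Plus by 2.77 ± 0.35 (adjusted p = 3.61e-05). TOM_I Plus fell from 60 and 107 to 16.6 and 27.8 (−1.85 ± 0.38, adjusted p = 0.00125). The other gypsy-group fall was TABOR_I Plus (−1.23, adjusted p = 0.00564; 0.0698 without XX replicate 2), named after its values were seen. In the LINE list, non-LTR retrotransposons, 45 of 60 rose and 15 did not pass (adjusted over the list alone 47; median 1.03; adjusted p = 0.00249; 0.236 with a replicate block, under which the gypsy list kept 0.0455). G2_DM Plus rose from 285 and 317 to 2291 and 1773 (2.74 ± 0.23, adjusted p = 1.76e-06), G2_DM Minus by 2.57 ± 0.21 and HELENA_RT Minus from 10 and 14.7 to 92.0 and 66.2 (2.59 ± 0.39, adjusted p = 0.000151). DOC4_DM Plus (2.64 ± 0.77, adjusted p = 0.0119) lost its call without XX replicate 1 (1.46, adjusted p = 0.0733) or XXYcongo replicate 2 (2.33, adjusted p = 0.0619).

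Of 26 DNA transposon features 21 rose and 5 did not pass in XXYcongo ovary (adjusted over the list alone 21; median 1.11; adjusted p = 0.00812; 0.180 with a replicate block). PROTOP Plus rose from 870 and 740 to 3900 and 5542 (2.53, adjusted p = 4.06e-06), PROTOP_B Plus by 2.51 (adjusted p = 2.61e-06) and POGO Minus from 256 and 208 to 1059 and 1547 (2.47 ± 0.27, adjusted p = 1.45e-05). TRANSIB3 Minus (2.12 ± 0.73, adjusted p = 0.0291) lost its call without XX replicate 2 (adjusted p = 0.135), XXYcongo replicate 1 (0.131) or XXYcongo replicate 2 (0.161). Of 32 mdg1 and mdg3 features 27 rose and 5 did not pass (adjusted over the list alone 27; median 1.35; adjusted p = 0.00812; 0.236 with a replicate block). MDG1_I Minus rose from 1531 and 1362 to 5333 and 4171 (1.71 ± 0.23, adjusted p = 6.47e-05) and MDG1_LTR Minus by 2.29 ± 0.38 (adjusted p = 0.000337). MICROPIA_LTR Minus (1.82 ± 0.60, adjusted p = 0.0218) lost its call without XX replicate 2 (0.86, adjusted p = 0.210) and STALKER3_LTR Plus (1.76 ± 0.51, adjusted p = 0.0116) without XX replicate 1 (1.31, adjusted p = 0.0637). TMM scaling ended the calls of DOC4_DM, TRANSIB3, MICROPIA_LTR and STALKER3_LTR. It gave 40 up and 2 down for gypsy (median 0.44), 14 and 1 for LINE (0.26), 9 up for DNA transposons (0.35) and 8 up for mdg1 and mdg3 (0.58). The lists that did not pass were copia (9 of 12 rose, adjusted over the list alone 10, adjusted p = 0.238) and BEL/Pao (14 of 27 rose, over the list alone also 14, adjusted p = 0.408). The BEL/Pao median was 0.73 as deposited and −0.01 with TMM, which called 2 up and 2 down. DNAREP1_DM Plus rose by 0.90 ± 0.29 (adjusted p = 0.0185; 0.119 without XX replicate 2, 0.0756 without XXYcongo replicate 2 and 0.671 with TMM) and DNAREP1_DM Minus differed by 0.48 (adjusted p = 0.196).

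Telomere retrotransposons went both ways in XXYcongo ovary: 4 of 8 features rose, 2 fell and 2 did not pass, and adjusted over the list alone 4 rose and 4 fell. TART Minus fell to 1899 and 1541 (−1.34 ± 0.22, adjusted p = 0.000337) and TART_B1 Minus fell (−1.20 ± 0.30, adjusted p = 0.00447). TAHRE Plus rose by 1.35 ± 0.26 (adjusted p = 0.000801), TAHRE Minus by 0.84 ± 0.22 (adjusted p = 0.00722), HETA Minus by 0.71 ± 0.22 (adjusted p = 0.0174) and HETA Plus by 0.66 ± 0.23 (adjusted p = 0.0331). TART Plus (−0.59 ± 0.26, adjusted p = 0.0746) and TART_B1 Plus (−0.73, adjusted p = 0.0768) did not pass. The list did not pass (adjusted p = 0.169), with a test downwards and a mean of −0.04 beside a median of 0.03. TMM scaling gave 0 up and 4 down by limma, with a median of −0.74, and turned HETA Minus to −0.07 and HETA Plus to −0.12. It also ended both TAHRE calls (0.58 and 0.06), while TART Plus (−1.37) and TART_B1 Plus (−1.50) passed. Both HETA calls ended without XX replicate 1 (adjusted p = 0.0935 for Minus and 0.0559 for Plus), XX replicate 2 (0.0731 and 0.203) or XXYcongo replicate 1 (0.0572 and 0.183). The TART_B1 Minus call ended without XX replicate 2 (adjusted p = 0.0640) and the TAHRE Minus call without XXYcongo replicate 1 (0.0649). Without XXYcongo replicate 1, TART Plus (−0.92, adjusted p = 0.01001) and TART_B1 Plus (−1.08, adjusted p = 0.00802) passed, as they did with a replicate block (adjusted p = 0.0490 for TART Plus and 0.0369 for TART_B1 Plus).

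Of 4 features of the rDNA retrotransposons R1 and R2, which insert into rRNA genes, 2 rose in XXYcongo ovary. R2_DM Minus rose from 128 and 94.4 to 339 and 293 (1.51 ± 0.28, adjusted p = 0.000623) and R1_DM Minus from 6742 and 6515 to 13066 and 9840 (0.77 ± 0.21, adjusted p = 0.0072). R1_DM Plus (0.42, adjusted p = 0.159) and R2_DM Plus (0.39, adjusted p = 0.346) did not pass, nor did the list (adjusted over the list alone 2 up, adjusted p = 0.781). The list median was 0.60 as deposited and −0.18 with TMM scaling, which put R1_DM Minus at −0.0007. R1_DM Minus lost its call without XX replicate 2 (adjusted p = 0.0630) or XXYcongo replicate 1 (adjusted p = 0.0994), and R1_DM Plus passed without XXYcongo replicate 2 (0.71, adjusted p = 0.0368).

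The 3 largest rises in XXYcongo ovary were of tRNA fragments, ahead of DMHMR1 Plus. tRNA:Pro-CGG-2-1 read 2 and 2.80 in XX and 329 and 429 in XXYcongo (6.80 ± 0.47, adjusted p = 4.54e-07). tRNA:Pro-AGG-1-6 rose by 6.31 ± 0.50 (adjusted p = 9.96e-07), tRNA:Pro-CGG-3-1 by 6.30 ± 0.61 (adjusted p = 4.59e-06) and tRNA:Pro-CGG-1-1 by 5.58 ± 0.47 (adjusted p = 1.74e-06). tRNA:Trp-CCA-2-3 rose from 7 and 7.69 to 414 and 146 (4.89 ± 0.45, adjusted p = 2.61e-06), tRNA:Gly-GCC-2-1 from 42 and 83.9 to 926 and 3273 (4.85 ± 0.50, adjusted p = 7.99e-06) and tRNA:Ser-AGA-1-1 from 4 and 0 to 39.0 and 56.0 (4.42 ± 0.85, adjusted p = 0.000879). These 7 were called up under all 6 scalings. Pro-CGG-2-1, Pro-AGG-1-6 and Trp-CCA-2-3 stand for 3, 7 and 6 entries with the same values, so the gene copy of origin is uncertain. By amino acid, a grouping outside the rule for named features, 5 of 5 proline profiles rose as deposited, 3 of 4 glycine, 5 of 6 glutamine and 3 of 3 aspartate profiles. So did 4 of 6 serine, 3 of 5 alanine, 3 of 5 arginine, 2 of 2 initiator methionine, 1 of 1 tryptophan, 1 of 2 valine and 1 of 7 leucine profiles. None of the 5 glutamate, 4 lysine or 10 tyrosine profiles was called by limma.

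Falls in XXYcongo ovary were mostly snoRNA, guides of rRNA modification. snoRNA:Me28S-G2703a read 575 and 767 in XX and 363 and 109.9 in XXYcongo (−1.73 ± 0.43, adjusted p = 0.00479), snoRNA:Psi18S-1377b fell by 1.52 (SE 0.41, adjusted p = 0.00784) and snoRNA:Psi18S-1086 went from 867 and 862 to 537 and 227 (−1.31 ± 0.36, adjusted p = 0.0085). snoRNA:Psi28S-1135d fell by 1.23 (SE 0.44, adjusted p = 0.0343). The mitochondrial gene mt:ND3 went from 35 and 45.5 to 18.2 and 13.7 (−1.29 ± 0.37, adjusted p = 0.0116), and the AAGAG satellite Minus strand read 12.4 and 0 (−3.43 ± 1.01, adjusted p = 0.0123). Without XX replicate 2 the calls of Me28S-G2703a (adjusted p = 0.0533), mt:ND3 (0.0775), AAGAG (0.0533) and Psi28S-1135d (0.102) ended. Without XXYcongo replicate 2 those of Psi18S-1086 (−0.69, adjusted p = 0.0856), Psi18S-1377b (−0.88, adjusted p = 0.0528) and AAGAG (−1.56, adjusted p = 0.173) ended. Without XX replicate 1 the AAGAG call ended (adjusted p = 0.0733), and so did Psi28S-1135d (0.0806), which also lost its call without XXYcongo replicate 1 (0.216), XXYohio replicate 1 (0.0515) or XXYohio replicate 2 (0.0528). With snoRNA total scaling the calls of mt:ND3 (adjusted p = 0.0525) and Psi28S-1135d (0.125) ended, and 7 snoRNA features fell and 5 rose in place of 25 and 1. With spike-in scaling none of these falls was called. The 1 snoRNA that rose was Me28S-C3227b (1.04 ± 0.30, adjusted p = 0.0114), named after its values were seen; its adjusted p was 0.0963 without XX replicate 2, 0.0543 without XXYcongo replicate 2 and 0.424 with TMM.

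The ovaries with the 2 added Y chromosomes had 21 calls in the same direction, 19 up and 2 down. Those up on both were led by DMHMR1 Plus, DMHMR1 Minus, Suste Minus, Chimpo_LTR Minus, QUASIMODO_LTR Plus and Chimpo_I Minus, with PROTOP_B Plus and PROTOP Plus from the DNA transposons. TART Minus and the AAGAG satellite Minus strand fell in both. QUASIMODO2-LTR_DM Minus was the 1 feature called in opposite directions, at −1.36 in XXYohio and 1.02 in XXYcongo (adjusted p = 0.0105). This opposition depends on the scaling: the XXYcongo rise was 0.24 with TMM (adjusted p = 0.504) and 0.26 with median-of-ratios (0.478), the XXYohio fall lost its call with snoRNA total scaling (0.0564), and with spike-in scaling the values were −0.094 and 1.93 and neither was called. The XXYohio call also ended without XX replicate 1, XX replicate 2 or XXYohio replicate 2, as given above. Independent lists of these sizes would share 9.10 up and 0.258 down, which is the reference for the 19 and 2 seen. Unchanged groups simulated against the same controls shared 0.02 on average (100 draws, at most 1). Such groups give few calls of any kind, so this value says little on the overlap of lists of these sizes. Across features the fold changes correlated at r = 0.30 (0.50 simulated), with a covariance of 0.29 against 0.0837 simulated, a difference of 0.207; features are not independent replicates. The 2 control libraries were not split between the contrasts, since each would keep 1 library, so part of the excess may come from the shared controls. The shared count was 31 without XXYcongo replicate 1 and 13 without XX replicate 2 or XXYohio replicate 2, and 14 without XX replicate 1.

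Tested directly, XXYcongo ovary had 355 features higher and 33 lower than XXYohio ovary, of which 247 and 5 were TE, 99 and 0 tRNA (33 of 73 profiles) and 2 and 25 snoRNA features. Suste Minus was higher by 0.80 (adjusted p = 0.0201) and DMHMR1 Plus by 0.85 (adjusted p = 0.0223), while PROTOP_B Plus differed by 0.39 (adjusted p = 0.171). With TMM these differences were 0.09 (adjusted p = 0.762), 0.14 (0.639) and −0.32 (0.151). The Suste Minus and DMHMR1 Plus calls also ended with median-of-ratios, non-spike total or spike-in scaling, without XXYohio replicate 1 (adjusted p = 0.130 and 0.0966) and without XXYcongo replicate 2 (0.226 and 0.141). QUASIMODO2-LTR_DM Minus was higher by 2.37 ± 0.29 (adjusted p = 6.09e-05; 1.67 with TMM, adjusted p = 0.0048). DNAREP1_DM was higher on both strands (Minus 1.62 ± 0.29, adjusted p = 0.000673; with TMM Minus 0.92, adjusted p = 0.0261, and Plus 0.63, adjusted p = 0.0544). Spike-in scaling ended the calls of QUASIMODO2-LTR_DM Minus and of DNAREP1_DM on both strands. In the lists, 85 of 113 gypsy features were higher and 3 lower (adjusted over the list alone 88 and 3; adjusted p = 1.87e-05), 47 of 60 LINE (alone 51; adjusted p = 0.00131) and 25 of 32 mdg1 and mdg3 (alone 26; adjusted p = 0.00249). So were 21 of 26 DNA transposon (alone 21; adjusted p = 0.0286) and 19 of 27 BEL/Pao features (alone 19; adjusted p = 0.0421), each with adjusted p = 0.998 with an estimated correlation. Copia (8 of 12 higher, alone 8, adjusted p = 0.260), rDNA retrotransposons (3 of 4, alone 3, adjusted p = 0.440) and telomere retrotransposons (5 higher and 2 lower of 8, alone the same, adjusted p = 0.930) did not pass. The median over all features was 0.83 as deposited and 0.14 with TMM; the counts were 142 up and 167 down with TMM, 136 and 171 with median-of-ratios and 263 and 91 with non-spike total scaling. With spike-in scaling and a replicate block 18 were called, all up. With TMM the TE calls were 76 up and 6 down and the tRNA calls 65 and 37, with identical tRNA entries each counted. By list TMM called 33 gypsy features higher and 3 lower, 7 LINE, 14 mdg1 and mdg3 and 3 BEL/Pao features higher, and 8 DNA transposon features higher and 1 lower. The snoRNA features lower numbered 110 with TMM, 114 with median-of-ratios, 61 with non-spike total and 8 with snoRNA total scaling. With TMM the BEL/Pao list no longer passed (adjusted p = 0.232). With non-spike total scaling neither BEL/Pao (adjusted p = 0.179) nor DNA transposons (adjusted p = 0.0734) passed, nor with a mean of at least 20 (0.0889 and 0.0507); without the filter DNA transposons did not (0.0804), and with a pseudocount of 5 or identical entries merged BEL/Pao did not (0.0568 and 0.0554). With a replicate block only the gypsy list passed (adjusted p = 0.0455), against 0.0543 for mdg1 and mdg3, 0.236 for LINE, 0.362 for DNA transposons and 0.562 for BEL/Pao.

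**Figure D3:**
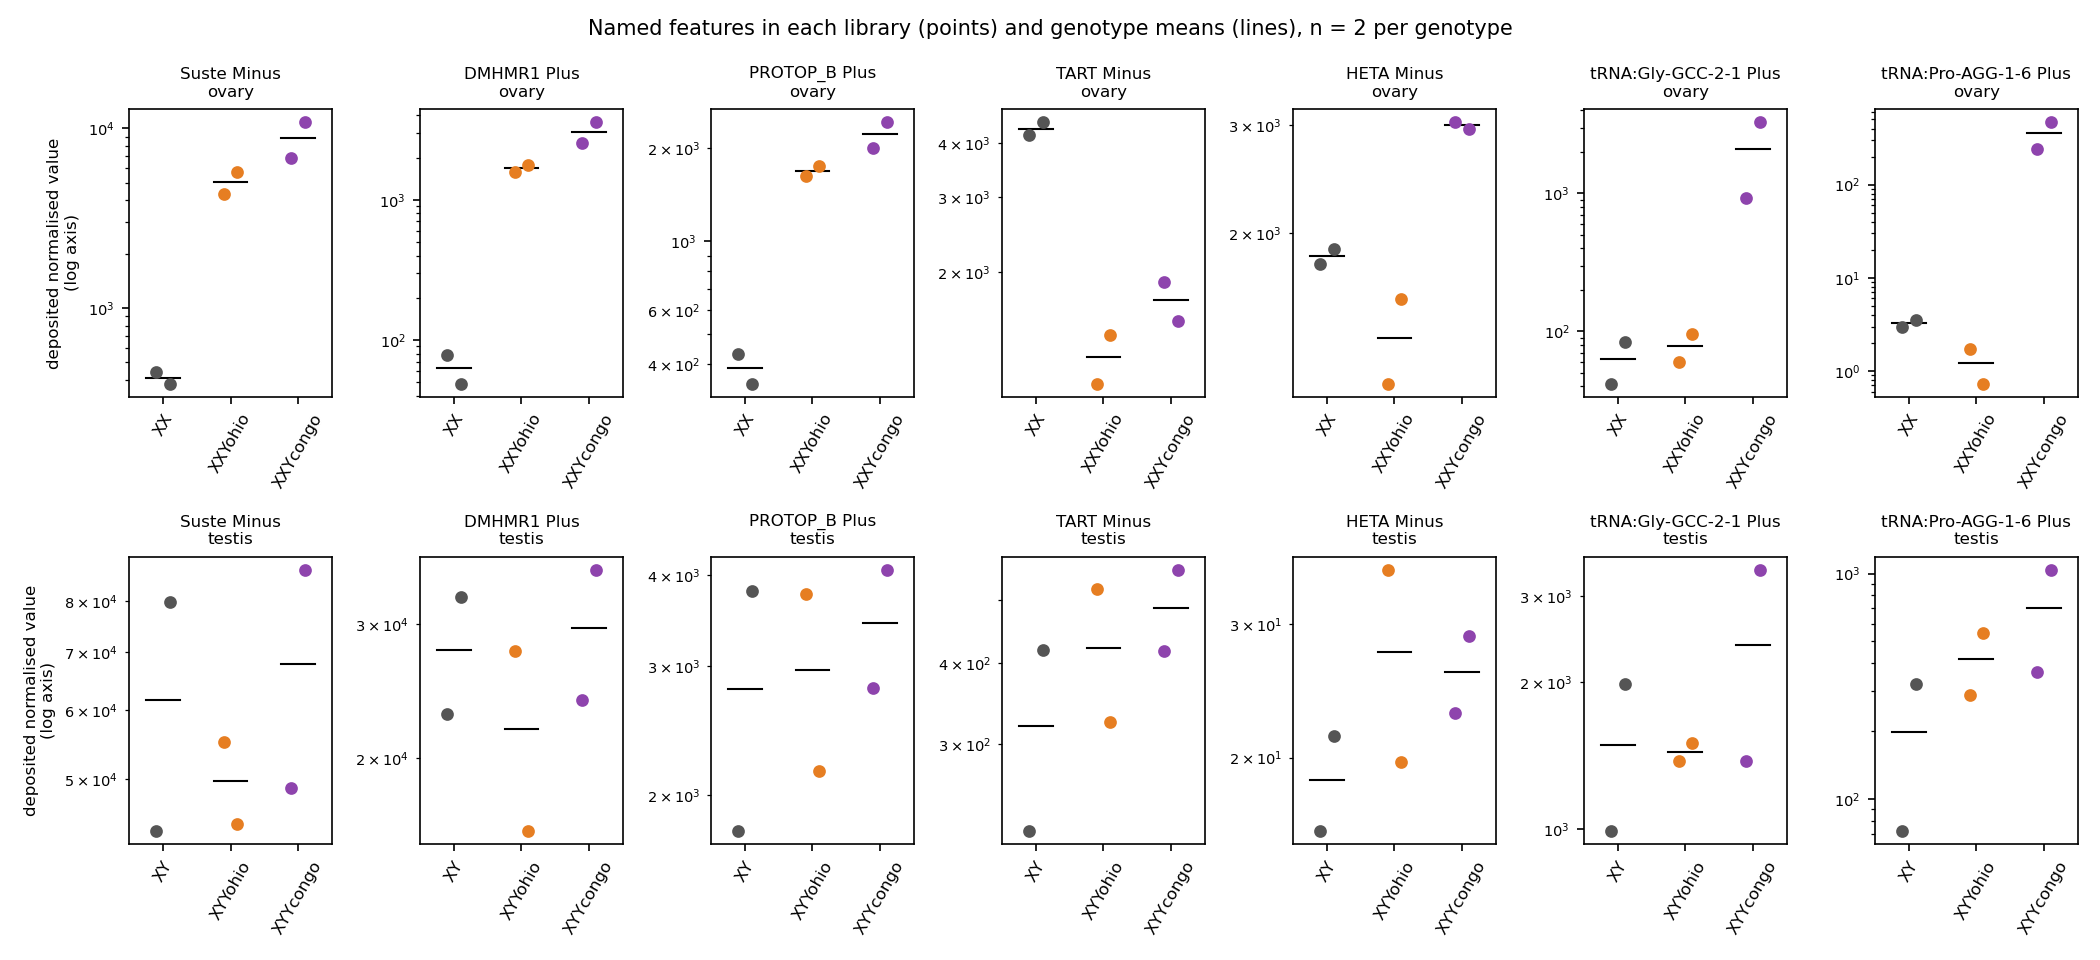
Deposited normalized values of named features in each library, grouped by genotype, with 1 panel per feature and a log axis of its own in each panel. Suste Minus lies between 381 and 440 in XX ovary and between 4291 and 10817 in the 4 XXY libraries.

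In testis the XYYohio genotype was compared with XY. The limma error of each testis feature came from the trend alone, so ± and p leave out that feature's own spread. Limma called 4 features up and 0 down of 618, with 30 at an unadjusted p under 0.05. These were AAGAC satellite Plus (0 and 63.3 in XY, 154 and 49.6 in XYYohio; 3.46 ± 0.66, n = 2 per group, adjusted p = 8.94e-05; libraries overlapping) and TOM_I Plus, a gypsy-group element (0 and 4.84, then 50.1 and 11.2; 3.37 ± 0.69, adjusted p = 0.000333). TABOR_I Plus, also of the gypsy group, rose from 1 and 6.85 to 64.9 and 19.2 (3.20 ± 0.67, adjusted p = 0.000346), and HELENA_RT Minus, a LINE, from 1 and 4.03 to 28.8 and 20.3 (2.99 ± 0.69, adjusted p = 0.00236). XY replicate 1 had the lowest value of each. Without it limma called 0, and the adjusted p of the 4 was 0.795 to 0.972. Without XYYohio replicate 1 their adjusted p was 0.138 to 0.474 and the 1 feature called was AAGAC Minus, named after its values were seen. With TMM, median-of-ratios and snoRNA total scaling limma called 0 (78, 78 and 19 at an unadjusted p under 0.05). The fold changes themselves stayed near the deposited ones. In the same order they were 3.75, 3.62 and 3.50 for AAGAC Plus and 3.61, 3.50 and 3.40 for TOM_I Plus. They were 3.34, 3.22 and 3.28 for TABOR_I Plus and 3.11, 3.00 and 3.07 for HELENA_RT Minus. edgeR called TOM_I Plus, TABOR_I Plus and HELENA_RT Minus (24 unadjusted) and DESeq2 called 0 (43 unadjusted).

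The features of smallest p that did not pass in XYYohio testis included Jockey Minus (1.85, adjusted p = 0.455) and ACCORD_I Minus (1.68, adjusted p = 0.634) on the higher side. On the lower side were ARS406_DM Plus (−2.21, adjusted p = 0.415), RSP Minus (−1.99, adjusted p = 0.380), GYPSY_I Minus (−1.84, adjusted p = 0.455) and QUASIMODO_LTR Minus (−1.76). No tRNA feature of 242 or snoRNA feature of 115 was called by limma (10 and 0 at an unadjusted p under 0.05). edgeR and DESeq2 called no tRNA feature either, with 3 and 25 at that level. Suste Minus read 43605 and 79771 in XY, 55125 and 44419 in XYYohio, and 48803 and 86915 in XYYcongo, at −0.25 and 0.14 against XY, and was not called.

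In XYYohio testis the BEL/Pao list passed downwards although none of its 20 features was called, over all features or adjusted over the list alone (median −0.27, adjusted p = 0.0353; adjusted p = 0.0649 with the replicate block and adjusted p = 0.998 with an estimated correlation). Its members of largest change were ROO_LTR Plus (−1.57), DIVER2_I Minus (1.21), DIVER2_LTR Minus (1.12) and ROO_LTR Minus (−1.11). The list did not pass without the filter (adjusted p = 0.0516) or with identical entries merged (adjusted p = 0.0991). The median was negative under all 6 scalings. The other lists did not pass: gypsy (2 of 78 rose, adjusted p = 0.930, with a median of −0.06 beside a mean of 0.15), LINE (1 of 36, adjusted p = 0.918), DNA transposons (16 features, adjusted p = 0.605), mdg1 and mdg3 (25, adjusted p = 0.547) and copia (10, adjusted p = 0.873, median 0.20 with a test downwards). The DNA transposon median of 0.02 stood beside a mean of −0.04. Nor did rDNA retrotransposons (4, adjusted p = 0.864) and telomere retrotransposons (8, adjusted p = 0.306, median 0.56). Adjusted over each list alone the counts were the same. DNAREP1_DM was not called (Plus −1.02, Minus 0.73).

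The XYYcongo testis had 7 features up and 3 down against XY by limma, with 60 of 618 at an unadjusted p under 0.05. As in XYYohio, the error behind each ± and p came from the trend alone, not from the feature's own spread. Neither edgeR nor DESeq2 called any of the 7 satellite features up. Satellite small RNAs made up 4 of the rises: AAGAC Plus went from 0 and 63.3 to 157 and 187 (4.43 ± 0.66, n = 2 per group, adjusted p = 1.24e-08), AAGAG Plus from 0 and 25.8 to 62.1 and 40.9 (3.31 ± 0.68, adjusted p = 0.000189), AAGAC Minus rose by 2.89 (adjusted p = 0.00257) and AAGAGAG Minus from 23 and 91.5 to 178 and 316 (2.34, adjusted p = 0.0290). The TE entries were those called in XYYohio: TOM_I Plus (3.78, adjusted p = 9.2e-06), TABOR_I Plus (3.69, adjusted p = 9.2e-06) and HELENA_RT Minus (2.96, adjusted p = 0.00226). RSP Minus, the Responder satellite, fell from 30 and 74.6 to 3.27 and 14.5 (−2.57 ± 0.67, adjusted p = 0.00923) and DM297_LTR Plus from 7 and 34.7 to 1.63 and 0.851 (−2.94 ± 0.72, adjusted p = 0.00384). satellite_ACCGAGTACGGG Minus read 7 and 13.3 in XY and 0 in both XYYcongo libraries (adjusted p = 0.00238), at least 4.06-fold lower against a floor of 3 reads per library.

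The XYYcongo testis calls also rest on XY replicate 1. Without it limma called 0 up and 2 down (RSP Minus and DM297_LTR Plus kept an adjusted p under 0.05), with TOM_I Plus at 2.51 (adjusted p = 0.207), TABOR_I Plus at 2.70 (0.0880), HELENA_RT Minus at 2.29 (0.402) and AAGAC Plus at 1.42 (0.996). Without XY replicate 2 it called 22 up, and RSP Minus (−1.93, adjusted p = 0.218), DM297_LTR Plus (−1.86, 0.387) and satellite_ACCGAGTACGGG Minus (adjusted p = 0.199) did not pass. Without XYYcongo replicate 1 the calls of AAGAGAG Minus (0.170) and RSP Minus (0.790) ended. Without XYYcongo replicate 2, 4 up and 2 down were left, and HELENA_RT Minus (0.0648), AAGAC Minus (0.241), AAGAGAG Minus (0.554) and DM297_LTR Plus (0.0987) did not pass. With TMM, median-of-ratios and snoRNA total scaling limma called 0 (88, 83 and 25 at an unadjusted p under 0.05). The fold changes themselves moved little. In the same order they were 4.38, 4.36 and 4.25 for AAGAC Plus, 3.72, 3.71 and 3.62 for TOM_I Plus, 2.07, 2.06 and 2.23 for AAGAGAG Minus and −2.83, −2.85 and −2.64 for RSP Minus. edgeR called 3 up, the TE entries, and 3 down, and DESeq2 called TABOR_I Plus alone. The median over all testis features was 0.25 as deposited, −0.008 with TMM and −0.16 with spike-in scaling. No tRNA or snoRNA feature was called by limma (32 and 5 at an unadjusted p under 0.05), and edgeR and DESeq2 called none either (32 and 31 tRNA and 2 and 2 snoRNA features at that level).

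No list passed in XYYcongo testis. In the gypsy list 2 of 78 features rose and 1 fell (adjusted p = 0.781), in the LINE list 1 of 36 rose (adjusted p = 0.864), and no member was called of BEL/Pao (adjusted p = 0.2501), mdg1 and mdg3 (0.556), DNA transposons (0.613), copia (0.864), rDNA retrotransposons (0.781) or telomere retrotransposons (0.367). Adjusted over each list alone the counts were the same. TART Plus differed by 0.89 in XYYohio and 0.82 in XYYcongo, and no TART, HETA, TAHRE, R1 or R2 feature passed in either. With TMM scaling the telomere list passed upwards in both genotypes (adjusted p = 0.0383 each) and BEL/Pao downwards in XYYcongo (adjusted p = 0.0383); with an estimated correlation as well, a combination chosen after seeing the data, these had adjusted p = 0.937 for the telomere list in both and 0.983 for BEL/Pao. DNAREP1_DM was not called (Plus −0.06, Minus 0.93).

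Of the testis calls, 4 were the same in both genotypes: AAGAC Plus, TOM_I Plus, TABOR_I Plus and HELENA_RT Minus, all up. Independent lists would share 0.0453. In 100 simulated draws of unchanged groups 0 were shared, but such groups give few calls of any kind. The simulated noise was independent between features, so no control library stood apart in it. Across features r was 0.77 (0.49 simulated), with a covariance of 0.41 against 0.225 simulated, a difference of 0.182. The 2 XY libraries were not split between the contrasts, since each would keep 1 library, so part of this overlap may come from the shared controls. The count was 0 without XY replicate 1 and 1 without XYYohio replicate 1. Tested directly, XYYcongo and XYYohio testes differed in no feature by limma (8 of 618 at an unadjusted p under 0.05), edgeR (7) or DESeq2 (4), and without XYYohio replicate 2 in 2, AAGAC Minus and AAGAGAG Minus, named after their values were seen. Of the named features, AAGAG Plus differed by 2.15 (adjusted p = 0.337), and the lowest adjusted p of any list was 0.613.

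Effects in ovary and testis were compared over the 591 features tested in both, by contrasts within each table. Expected counts are of calls in the same direction, whereas Fisher's exact test took calls in either direction and does not test agreement in direction. For Yohio none was called in the same direction (20 called in ovary and 3 in testis by limma, 0.0863 expected from independent lists, Fisher's exact test two-sided p = 1), with r = 0.065 and Spearman's rho 0.14 across features. For Ycongo HELENA_RT Minus rose in both tissues, with 329 and 6 called and 1.67 expected (Fisher's exact test p = 1; r = 0.27, rho 0.24); its testis call ended without XY replicate 1 (adjusted p = 0.402) or XYYcongo replicate 2 (0.0648). TOM_I Plus and TABOR_I Plus were called in opposite directions, TOM_I Plus at −1.85 in ovary and 3.78 in testis and TABOR_I Plus at −1.23 and 3.69; the testis rises ended without XY replicate 1 (adjusted p = 0.207 and 0.0880). Features are not independent replicates.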

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

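The tests of explanations below, with their bounds, were all chosen after the result they concern was seen, whereas the contrasts themselves were fixed before.

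Direct contrasts of the added Y chromosomes drew attention in ovary, where 388 features differed between XXYcongo and XXYohio as deposited. With TMM 309 were called, 175 of them among the 388 in the same direction. Spike-in scaling with a replicate block called 18. QUASIMODO2-LTR_DM Minus differed by 2.37 on the log2 scale (1.67 with TMM). As deposited it was called in opposite directions from XX, but its XXYcongo rise was 0.24 with TMM (adjusted p = 0.504), and with spike-in scaling neither side was called. For Ycongo, TOM_I Plus and TABOR_I Plus were lower than the control in both ovary libraries and higher in both testis libraries. Their testis fold change minus their ovary fold change was 5.63 for TOM_I Plus and 4.92 for TABOR_I Plus on the log2 scale, and this difference between tissues was not tested. Without XY replicate 1 the testis calls ended (adjusted p = 0.207 for TOM_I Plus and 0.0880 for TABOR_I Plus), and without XX replicate 2 the ovary call of TABOR_I Plus ended (adjusted p = 0.0698). The XXYohio call of QUASIMODO2-LTR_DM Minus ended without XX replicate 1 (0.113), XX replicate 2 (0.1002) or XXYohio replicate 2 (0.124). Spike-ins, which enter only the spike-in scaling, took 51.7%, 74.2% and 76.3% of the reads of replicate 1 of XY, XYYohio and XYYcongo testis and 36.2%, 17.58% and 24.4% of those of replicate 2, so the genotypes did not keep their order.

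Suste and DMHMR1 small RNAs were higher in the ovaries with either added Y. Scale factors cannot account for it: the Suste to TE ratio, which no factor moves, was in the lowest XXY library 5.98 times that of the highest XX library. Testis RNA in the XXYohio ovary libraries is argued against, since of 5 features abundant in testis (XY mean at least 200 and at least 20 times XX ovary) the median rise was −0.158 times the rise that the Suste Minus change would need, and 0.139 times over a wider set of 19 (XY mean at least 50 and at least 5 times XX ovary). In XXYcongo the same medians were 2.77 and 5.68, above what testis RNA alone predicts; of the 5 features, 4 tRNA features lay above 1 and AAGAG satellite Minus at −0.217, and with 1 of the 5 not a tRNA this explanation cannot be told apart there. Expression from the added Y chromosome, the difference the design names, stays open as a hypothesis for both genotypes and was not tested.

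TE small RNAs were higher in the XXYcongo ovary. A wrong scale factor would leave ratios within a library in place, yet the lowest XXYcongo TE to snoRNA ratio was 1.90 times the highest of the other 4 ovary libraries. The 45S rDNA fragments alone cannot account for it either, as the lowest XXYcongo TE share without 45S_rDNA Plus was 6.83 percentage points above the highest of the others (67.0% and 60.2%). Fewer snoRNA and rRNA fragments rather than more TE small RNAs cannot be told apart from a TE gain. The lowest XXYcongo TE to tRNA ratio, with each identical tRNA entry counted, was 0.854 times the highest of the others, and no class is known to be constant. The genotype itself stays open and was not tested apart from these.

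Fragments of some tRNAs were higher in the XXYcongo ovary. Identical gene copies listed separately do not make the count, since 31 distinct profiles were called, and a uniform gain is excluded by a spread of log2 fold changes 3.73 times their median standard error. Testis RNA is argued against as the whole source of the called rises: over the 31 called profiles the median rise was 8.56 times what the Suste Minus rise allows, with a range of 1.99 to 28.5. These profiles were taken because they were called up, which raises the median, and the 42 not called were left out. RNA of another tissue stays open, because no marker list had a tested feature, and so do library steps that depend on fragment length, on which the tables hold no data. The added Y chromosome stays open too and was not tested apart from them.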

How the results depend on the processing

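Scaling to snoRNA, non-spike or spike-in totals, merging identical entries and leaving out testis libraries with a replicate block were chosen after seeing the data; the rest was planned. Of 126 named features and contrasts, all kept direction and side of the threshold with a pseudocount of 0.5 or no filter. The 126 include features not called in the main fit, which had no call to lose. Calls lost numbered 1 with a pseudocount of 5, 5 with edgeR, 16 with DESeq2 and 12 without the trend. TMM ended 21 calls and both ended and reversed 3 more. Median-of-ratios scaling ended 22 and reversed 2 more. Scaling to the snoRNA total ended 19. Spike-in scaling with a replicate block ended 34 and reversed 1 more. In simulated data limma called 10% of features changed 2-fold in XYYcongo testis and 50% in XXYcongo ovary. Where no reason is given, the cause was not tested.

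In XXYohio ovary (26 calls) limma without the trend gave 14. In testis, XYYohio (4 calls) had 2 with a mean of at least 20, and 0 with TMM, median-of-ratios or snoRNA total scaling and with DESeq2. XYYcongo (10 calls) had 5 with a mean of at least 20, 0 with TMM, median-of-ratios or snoRNA total scaling, 6 with edgeR, 1 with DESeq2 and 22 at an adjusted p under 0.1, a looser threshold. With these scalings the prior degrees of freedom in testis fell from infinite to 2.96, 3.16 and 10.1. The 4 calls shared in testis became 2 with a mean of at least 20 and 0 with TMM or median-of-ratios scaling. The 1 feature shared by ovary and testis became 0 with a mean of at least 20, TMM or median-of-ratios scaling, and 13 at an adjusted p under 0.1. Of 11 list tests passed, 0 passed with an estimated correlation. Reversed values were R1_DM Minus with TMM (−0.00070), HETA Minus with TMM (−0.067) and median-of-ratios (−0.056), and HETA Plus with the same (−0.12 and −0.11), all in XXYcongo ovary.

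Same-numbered ovary libraries deviated together at r = 0.016, 0.065 and 0.25, not above 0.1 in each pair, so the block stayed an alternative there. However, 24 features were called between the numbers. Spike_1 took at least 29.8% of spike-in reads in every library numbered 1 and at most 0.814% in those numbered 2. For the spike-ins the numbers therefore mark sets in ovary too, and the main ovary fit does not model them. The replicate block gave 42 calls in XXYohio ovary and 32 shared between the ovaries, 2 shared by ovary and testis, and 3 list tests passed (telomere retrotransposons in XXYohio, gypsy against XX and against XXYohio). In testis, where the numbers pair libraries, the block changed no call except BEL/Pao in XYYohio. Spike-in scaling with a replicate block gave 2, 95 and 18 calls in the ovary contrasts XXYohio against XX, XXYcongo against XX and XXYcongo against XXYohio, 2 shared between ovaries and 0 shared by ovary and testis. It put DMRT1C Minus in XXYohio at 0.0087.

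Leaving out 1 library, whose lone partner is then assumed to vary like the other groups, gave 15 to 40 calls in XXYohio ovary and 286 to 387 in XXYcongo ovary. It gave 275 to 401 between these and 13 to 31 shared. In testis it gave 0 to 6 in XYYohio (0 without XY replicate 1, 1 without XYYohio replicate 1), 2 to 22 in XYYcongo (2 without XY replicate 1, 22 without XY replicate 2), 0 to 2 between them and 0 to 6 shared. With the replicate block as well, 1 residual degree of freedom is left, and testis counts ran from 0 to 69 in XYYohio, 0 to 57 in XYYcongo, 0 to 50 between them and 0 to 39 shared.

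Without 45S_rDNA Plus, the TE share was 58.3%, 59.4% and 69.3% in XX, XXYohio and XXYcongo ovary and 39.0%, 37.2% and 38.7% in XY, XYYohio and XYYcongo testis. The tRNA share was 16.5%, 16.5% and 16.9%, then 31.2%, 36.1% and 32.5%, and the snoRNA share 22.8%, 20.9% and 10.4%, then 4.52%, 4.18% and 4.24%. All rise because the total is smaller.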

Other observations

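The class tests and the tRNA relation below were chosen after the result was seen.

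Both main snoRNA kinds took part in the lower snoRNA values of the XXYcongo ovary. Of 68 snoRNAs named for methylation sites 13 fell and 1 rose (median −0.30), of 72 named for pseudouridine sites 10 fell (median −0.37), and of 52 others 2 fell (median −0.20). As a class they passed camera's test downwards (adjusted p = 1.17e-38 preset, adjusted p = 0.103 with an estimated correlation), and the median turned positive with spike-in scaling. By the same camera test the TE class passed upwards (adjusted p = 1.31e-25 preset, 0.378 with an estimated correlation). The tRNA class did not pass (0.0520 preset, 0.999 with an estimated correlation). Of 12 mitochondrial mRNA features, mt:ND3 and mt:ATPase6 fell and 10 were not called (median −0.53, adjusted p = 0.00014 preset and adjusted p = 0.55 with an estimated correlation), with a median of 0.38 with spike-in scaling. TMM scaling called 9 of the 12 down, and snoRNA total scaling ended the calls of mt:ND3 (adjusted p = 0.0525) and mt:ATPase6 (0.0885). mt:tRNA:Ile-GAT (2.13, adjusted p = 0.0259) and mt:tRNA:Lys-CTT (1.40, adjusted p = 0.0485) rose. mt:ATPase6 and both mitochondrial tRNAs were named after their values were seen. Without XX replicate 2 the calls of mt:ND3 (adjusted p = 0.0775), mt:ATPase6 (0.0908) and mt:tRNA:Ile-GAT (0.152) ended, without XX replicate 1 that of mt:tRNA:Lys-CTT (0.483), and without XXYcongo replicate 2 those of mt:ATPase6 (0.0665), mt:tRNA:Ile-GAT (0.315) and mt:tRNA:Lys-CTT (0.161). TMM scaling ended both tRNA calls (adjusted p = 0.150 and 0.454).

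In testis, satellites passed upwards as a class of 7 features in XYYohio (adjusted p = 0.00383), XYYcongo (adjusted p = 2.17e-06) and the contrast of the 2 (adjusted p = 0.00383). With an estimated correlation the adjusted p was 0.376, 0.241 and 0.376. The class median was 0.85 in XYYohio and 2.34 in XYYcongo and positive under all 6 scalings. AAGAC Plus was at 0 in XY replicate 1, and without that library its adjusted p was 0.972 in XYYohio and 0.996 in XYYcongo. TE small RNAs of the Plus strand made up 26.02% to 28.9% of TE values in ovary libraries and 56.0% to 58.7% in testis libraries, or 41.6% to 48.2% in testis without DMHMR1.

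The 6 spike-ins came in different proportions by replicate number in both tissues. Spike_1 took 29.8% to 87.1% of spike-in reads in libraries numbered 1 and 0.0374% to 0.814% in those numbered 2, while Spike_5 took 0.0664% to 0.545% and 7.05% to 32.9%. Spike-in scaling was therefore run only with a replicate block.

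A hypothesis on the tRNA fragments is that those gaining most in the XXYcongo ovary are those relatively abundant in testis. Across 73 distinct profiles the log2 fold change of XXYcongo against XX correlated with the log2 ratio of XY testis to XXYohio ovary, a group outside the fold change, at Spearman's rho 0.672 (Pearson's r 0.83). No tRNA feature was called by limma between XXYohio and XX, so both quantities subtract a similar ovary level for each profile. That shared term can by itself give a positive correlation, so the rho cannot decide the hypothesis. Profiles are not independent replicates and the 2 tables were normalized separately, which shifts the ratio by about a constant. The relation may reflect the shared ovary term alone, or a tRNA fragment profile common to testis and the XXYcongo libraries, from biology or from library preparation. It was found and tested on the same data. By amino acid, proline profiles had a median log2 fold change of 6.30, tryptophan 4.89 and glycine 3.74, against 0.07 for glutamate and −0.02 for lysine.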
